A study of Caenorhabditis elegans with 2 samples.

How the data were processed

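Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole hermaphrodite young adults of the transgenic C. elegans strain YL557, 48 hours after release from starvation as L1 larvae. The strain expresses HRDE-1 (WAGO-9) with a C-terminal GFP-FLAG tag, and chromatin, fragmented by sonication, was precipitated with an antibody against GFP according to the sample description. The antibody field of the labels reads hrde-1, and the description was followed. The labels give 1 group with 2 biological replicates, so no comparison between groups was possible. Replicate numbers are those of the labels.

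The authors called candidate sites from each replicate and from the pooled reads with a control alignment. They also gave a list thresholded by reproducibility between replicates (irreproducible discovery rate, IDR), whose sites are called IDR peaks here. The signal values are the score the authors' caller gave each site against the control, on a scale that is not stated. They were used here only to describe, rank and filter sites within 1 list. The deposited lists also hold a column taken here as −log10 q by the usual layout of such lists, which nothing in the sources states. Its highest value was shared by all 1341 IDR peaks and by 259 pooled candidates outside the IDR list, and it was used only for that description. The aligner, the caller, their versions and the IDR threshold are not given in the sources used here. Read depth per sample is unknown, because the lists hold no read counts, so no interval is given for a signal value. The control was not analysed here.

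Lists on genome build ce11 were used for all main results. Lists on ce10, an earlier build, were used only as alternatives, for the count of peaks and for the comparisons of the replicates. No coordinates were converted between builds. Positions count from 1. Chromosome lengths of the lists were checked against the reference genome WBcel235 and its Ensembl annotation, release 115, with 46926 genes. Gene symbols missing there were taken from the RefSeq annotation of the same assembly for 4141 genes. Mitochondrial gene names are those of RefSeq.

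The IDR peaks were compared with background candidates, the sites of the pooled ce11 list whose summits lay over 500 bp from every IDR peak. This gave 27924 background candidates, and 735 candidates nearer to an IDR peak that were not in the IDR list were left out. The IDR peaks were by construction the strongest pooled candidates, so every comparison with this background also compares strong with weak sites. Sites were taken as independent, which neighbouring summits in 1 interval are not: the 1341 peaks had 1319 distinct intervals. Sites at near-identical gene copies, such as tRNA genes, may share reads and then are not independent either. Genes were also taken as independent, though 1 summit can lie at several genes. The intervals and p-values do not allow for this.

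A site was at a gene start when its summit lay within 500 bp of the annotated start of a gene on either side. It was at a 3′ end when it lay within 500 bp of the annotated end of a protein-coding gene. Exon and intron summits lay inside an annotated gene, in an exon of any gene or in none. Arms were the outer terciles of each of the 5 autosomes by length. Repeats were the soft-masked bases of the genome. For exclusive classes, a peak was assigned in the order mitochondrial, tRNA, snoRNA, snRNA, protein-coding start, protein-coding 3′ end. Shares were compared by two-sided Fisher's exact tests, with Clopper-Pearson 95% intervals for shares and exact conditional intervals for odds ratios. Gene types with at least 10 annotated genes were tested together (11 types) with Benjamini-Hochberg adjustment, and the threshold was an adjusted p of 0.05.

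Gene lists were fixed before the data were examined, some by name and some by symbol pattern: germline nuclear RNAi targets, small RNA pathway, germ granule, heterochromatin and histone methylation, meiosis, oocyte and maternal, sperm, major sperm proteins, intestine, muscle, neuron, hypodermis and cuticle, collagens, ribosomal proteins, histones, abundant genes of translation and the cytoskeleton, heat shock, nuclear hormone receptors, chemoreceptors, F-box, C-type lectins, MATH and BATH, and the transgene loci hrde-1 and unc-119. The names were listed from general knowledge. Of the listed names, cde-1 and rad-54 matched no gene. The 22 lists with at least 5 genes were tested against all other protein-coding genes, and some genes stand in more than 1 list (wago-4 is in the small RNA and germ granule lists). Lists were tested as wholes and not gene by gene. The rule for named genes, also fixed before the data were examined, took the 25 IDR peaks with the highest signal, each with the gene starts of each type within 1000 bp. It also took up to 4 genes with the highest signal at their start from each called list and from each list of germline, small RNA, heterochromatin and transgene genes, with hrde-1 and unc-119 in any case. Other names in the text were chosen after their values were seen.

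The replicates were compared by Spearman's rho across IDR peaks, with the strongest candidate of each replicate whose summit lay in the peak, and by the share of IDR peaks found among the top 1341 candidates of each replicate. Shares per replicate used the top 1341 candidates of that replicate against the rest of its own list. Median signal, GC content and rho were tested with 100000 permutations, two-sided. GC content was taken in 200 bp around the summit. The 6-mers, with both strands merged, were counted as present or absent in the same 200 bp and compared with background drawn in bins of 5 percent GC and by nearness to a gene start, with up to 5 candidates per peak. The neighbourhoods of hrde-1 and unc-119, 20 kb on either side, were compared with 10000 random autosomal windows of the same size. The random seed was 1 throughout.

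The alternatives chosen before the data were examined were the ce10 list, the stronger IDR peaks by signal (670), merged peaks, each replicate alone, windows of 200 bp and 1000 bp, the whole interval in place of the summit, other definitions of gene hits and arms, other backgrounds, a sequence window of 100 bp, other overlaps between replicates, and transgene windows of 10 kb and 50 kb. Chosen after the data were examined were the results on 3′ ends, the results and alternatives for single gene types other than tRNA (the test of all types together was planned), the results on X by class of site, the removal of mitochondrial peaks or of sites at tRNA, snoRNA and snRNA genes, and random nuclear positions as background for X.

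The steps were tested on simulated data. With no effect planted, location tests gave 7 calls in 140 tests, and tests of gene types, gene lists and 6-mers gave 0 calls in 220, 440 and 6240 tests. The simulated sites and genes were drawn independently, so these counts do not cover summits shared by neighbouring genes or near-identical gene copies. All 200 sites planted at tRNA genes were counted there, all 5 planted lists were called, and the planted 6-mer ranked first. The tRNA sites were planted within 500 bp of the starts, so their count checks only the counting. Planted lists had a higher share of genes with a peak than any list in the main comparison at gene starts. Power at the shares seen there was not measured. Tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.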

Results

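The data were chromatin immunoprecipitation followed by sequencing (ChIP-seq) of HRDE-1, also called WAGO-9, a nuclear Argonaute protein that binds small RNAs in the germ line. HRDE-1 is known for inherited silencing of genes and transposons. Strain YL557 carries HRDE-1 with a GFP-FLAG tag at its C-terminus, and by the sample description chromatin was precipitated with an antibody against GFP. The antibody field of the labels reads hrde-1 instead, and the text follows the description. Whole hermaphrodite young adults were collected 48 hours after starved L1 larvae were released to grow. There was 1 group with 2 biological replicates. The data were lists of called sites: 24269 candidate sites for replicate 1, 30000 for replicate 2 and 30000 for the pooled reads. A further list held the 1341 sites the authors kept after a threshold on reproducibility between replicates (irreproducible discovery rate, IDR). Those were the pooled candidates with the highest signal, so the list does not show that each site was reproduced in both replicates. Read depth per sample is unknown, so the intervals given are for counts of sites and genes and cover counting error only. Signal values are the authors' scores, on a scale that is not stated, and are used to rank sites within 1 list. With 1 group, the comparisons were between the 1341 IDR peaks and the 27924 background candidates. Background candidates were sites of the pooled list, outside the IDR list, whose summits lay over 500 bp from every IDR peak. No control was analysed here.

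The first question was where in the genome tagged HRDE-1 chromatin was recovered. The strongest sites of all lay in the mitochondrial genome, which held 17 of the 25 highest signal values. These lists alone do not show that HRDE-1, a nuclear protein, binds mitochondrial DNA, since no control was analysed here. Among the 1319 nuclear peaks, chromosomes III and I were the densest, with 19.0 and 18.2 peaks per Mb, followed by IV with 15.3, II with 13.4 and V with 9.13. Chromosome X was the sparsest, with 6.66 peaks per Mb. The IDR peaks were the 1341 pooled candidates with the highest signal, 4.47% of that list. Their median width was 456 bp (range 114 to 3596 bp), and their signal values ran from 73.95 to 6146 with a median of 100.6. The highest nuclear value was 406.7.

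Mitochondrial DNA was covered over most of its length rather than at single places. The 22 mitochondrial IDR peaks came from 23 pooled mitochondrial candidates, whose intervals covered 86.8% of the 13794 bp genome. The covered share was 51.1% in replicate 1 and 88.97% in replicate 2. The top summit of the whole list lay at position 4700 in CYTB (cytochrome b), with a signal value of 6146, and the top summit of each replicate list lay at 4699 or 4700. Other mitochondrial summits among the strongest 25 lay in ND5 (position 12447, signal 4313), COX3 (6096, signal 3315), ND4 (7302, signal 2397) and the small ribosomal RNA gene (1092, signal 1838). Of the 19 mitochondrial summits of replicate 1, 17 lay within 50 bp of one in replicate 2.

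IDR peaks lay at the starts and 3′ ends of genes and were scarce elsewhere in the nuclear genome. When each peak was given 1 place, 451 lay at protein-coding starts, 436 at protein-coding 3′ ends, 197 at tRNA genes, 98 at snoRNA genes and 38 at snRNA genes. A further 22 were mitochondrial, and 99 peaks (7.38%) lay elsewhere, against 57.7% of background candidates. In the top 1341 candidates of each replicate, protein-coding starts held 34.2% ± 2.11 and protein-coding 3′ ends 33.2% ± 1.85 (SD, n = 2).

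Summits lay within 500 bp of a gene start of any type for 857 of 1341 IDR peaks, or 63.9% (95% exact interval 61.3 to 66.5%), against 33.6% of background candidates. The odds ratio was 3.51 (3.12 to 3.94; two-sided Fisher's exact p = 3.5e-108). The share was 61.9% ± 1.74 (SD, n = 2) in the replicates' own top candidates. Introns held 10.96% of IDR summits against 32.9% of the background (odds ratio 0.252, exact p = 3.4e-75), and the space between genes held 42.7% against 25.5% (odds ratio 2.17, exact p = 3.2e-40). Soft-masked repeats held 19.7% against 34.2% (odds ratio 0.472, exact p = 2.1e-30). Exons held 46.4% against 41.6% (odds ratio 1.21, exact p = 0.000603). The exon difference was lost against the upper tercile of the background by signal (odds ratio 1.02, exact p = 0.747).

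**Figure D1:**
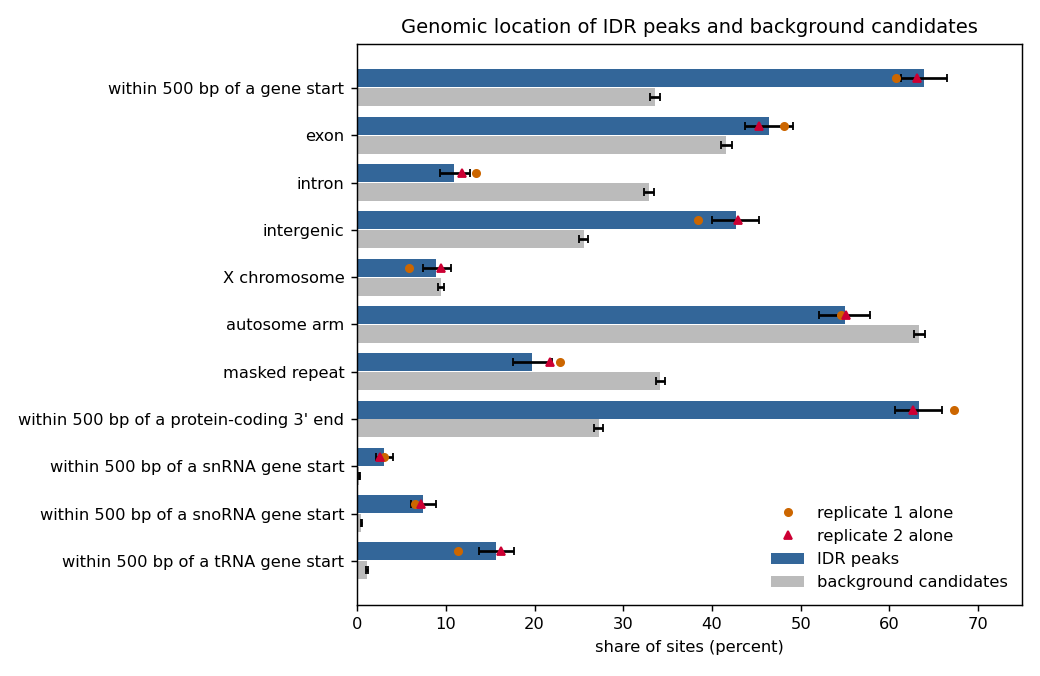
Share of sites (percent) in each kind of location for IDR peaks (blue bars) and background candidates (grey bars), with 95% exact binomial intervals. Circles and triangles give the top 1341 candidates of replicate 1 and of replicate 2; gene starts held 60.7% of these in replicate 1 and 63.2% in replicate 2.

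More IDR peaks lay at the 3′ ends of protein-coding genes than at their starts, which held 539. Starts of any gene type held 857, and a peak can lie at both a start and a 3′ end. Summits lay within 500 bp of an annotated 3′ end for 849 peaks, or 63.3% (60.7 to 65.9%), against 27.2% of background candidates, an odds ratio of 4.61 (4.11 to 5.18; Fisher's exact p = 1.9e-158). The share was 67.3% in the top candidates of replicate 1 and 62.7% in those of replicate 2. Among nuclear peaks, 41.4% of summits lay from 0 to 250 bp downstream of the nearest 3′ end, against 10.99% of background summits. The stretch of 250 bp upstream of the nearest protein-coding start held 16.6% of peak summits and 7.09% of background summits. At the level of genes, 592 of 19985 protein-coding genes (2.96%) had a peak at the start, 1081 (5.41%) had one at the 3′ end, and 173 had both. This comparison was chosen after the data were examined. Trans-splicing and operons, common in this species, can place annotated starts away from where transcription begins.

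**Figure D2:**
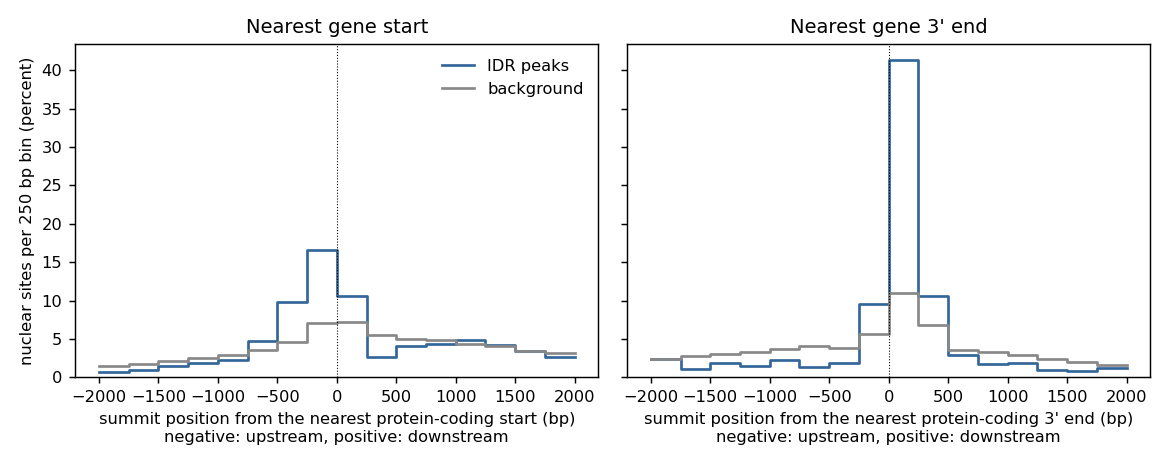
Position of nuclear IDR summits (blue) and background summits (grey) relative to the nearest protein-coding start (left) and 3′ end (right), as percent of sites per bin of 250 bp. The highest bin, 0 to 250 bp downstream of a 3′ end, held 41.4% of IDR summits and 10.99% of background summits.

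Genes of small structural RNAs stood out most. tRNA genes lay within 500 bp of 210 IDR peaks (15.7%, interval 13.8 to 17.7%), against 1.14% of background candidates, an odds ratio of 16.06 (13.3 to 19.4; adjusted exact p = 1.2e-140). Some of these peaks are mitochondrial, while the background holds no mitochondrial site; without mitochondrial peaks the share was 14.9% and the odds ratio 15.19 (12.5 to 18.4). snoRNA genes, whose RNAs guide modification of ribosomal RNA, lay at 99 peaks (7.38% against 0.487%, odds ratio 16.3, adjusted exact p = 2.0e-68). snRNA genes, whose RNAs act in splicing, lay at 40 peaks (2.98% against 0.265%, odds ratio 11.6, adjusted exact p = 1.2e-24). Only tRNA genes were planned as a result of their own; the other types were part of the same planned family of tests and were singled out after the data were examined. Of the nuclear genes, 232 of 612 tRNA genes (37.9%), 89 of 346 snoRNA genes (25.7%) and 31 of 129 snRNA genes (24.0%) had an IDR peak at their start.

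Of 11 gene types tested by Fisher's exact test, 7 passed an adjusted p of 0.05, 6 of them with a peak at a nuclear gene. Besides the 3 above these were other non-coding RNA genes (18.5% against 5.97%, odds ratio 3.57, adjusted exact p = 7.4e-52), protein-coding genes (40.2% against 24.4%, odds ratio 2.09, adjusted exact p = 3.6e-35), miRNA genes and rRNA genes. miRNA genes lay at 11 peaks (odds ratio 2.35, adjusted exact p = 0.0273). rRNA genes passed only through 4 mitochondrial peaks; the background held no mitochondrial site, so this comparison has no meaning, and 0 of 20 nuclear rRNA genes had a peak. piRNA genes, whose products feed the pathway in which HRDE-1 acts, lay at 2.09% of IDR peaks and 3.03% of background candidates (odds ratio 0.682, adjusted exact p = 0.0665; 0.609, adjusted exact p = 0.0164, in replicate 2 alone). Antisense RNA genes (2 peaks, odds ratio 0.946, but 1.43 and 1.60 in the single replicates), lincRNA genes (1.24) and pseudogenes (0.875) did not pass. The tRNA odds ratio depended on the replicate, with 7.78 in replicate 1 alone and 16.6 in replicate 2 alone, and was 7.23 against the upper tercile of the background. Many tRNA genes are near-identical copies, so which copy a read came from is uncertain. Peaks at such copies may not be independent sites, and the intervals and p-values for tRNA genes do not allow for that.

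Among protein-coding genes, those of 6 lists had peaks within 500 bp of their starts more often than other genes. These were the lists of oocyte and maternal, germ granule, heterochromatin and histone methylation, histone, ribosomal protein, and other abundant genes. Summits at 3′ ends were not left out, so in short genes the start window can also hold a peak at the 3′ end. Of ribosomal protein genes, 56 of 81 had a peak at the 3′ end. Chemoreceptor, nuclear hormone receptor, F-box and C-type lectin genes had them less often. Of 22 lists of at least 5 genes fixed before the data were examined, 10 passed an adjusted p of 0.05 in two-sided Fisher's exact tests, 6 higher and 4 lower. Oocyte and maternal genes had the highest share, with 10 of 36 genes (27.8%, interval 14.2 to 45.2%) against 2.92% of other protein-coding genes (odds ratio 12.8, adjusted exact p = 4.5e-07). Translation, cytoskeleton and other abundant genes came next with 6 of 25 (24%, odds ratio 10.4, adjusted exact p = 0.000397), and then ribosomal protein genes with 17 of 81 (20.99%, odds ratio 8.93, adjusted exact p = 2.0e-09). With a window of 200 bp only 2 lists passed, oocyte and maternal genes (odds ratio 7.89, adjusted exact p = 0.0264) and chemoreceptors (0.0447, adjusted exact p = 5.5e-07). Ribosomal protein genes had 4 of 81 with 200 bp (odds ratio 3.27, adjusted exact p = 0.172) and 42 of 81 with 1000 bp (51.9%, odds ratio 24.9, adjusted exact p = 2.1e-34). With the 670 stronger IDR peaks only 4 lists passed: oocyte and maternal, ribosomal protein, abundant and chemoreceptor genes.

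The oocyte and maternal genes with the highest signal at their starts were cpg-1 (III 4489359 to 4491392, signal 214.5, summit 240 bp upstream), which encodes an eggshell chondroitin proteoglycan, puf-11 (signal 154.8), a PUF family RNA-binding protein gene, chs-1 (signal 120.1), which encodes chitin synthase, and rme-2 (signal 111.8), the yolk receptor gene. The ribosomal protein genes were led by rpl-3 (III 3867854 to 3869587), with a summit at 3867555, 299 bp upstream of the start, and a signal of 406.7, the highest in the nuclear genome. rpl-18A (signal 306.0), rpl-35 (233.1) and rpl-37A (222.9) followed, the last with its summit 479 bp downstream of the start and 204 bp past the 3′ end. The abundant genes were led by tbb-1 (signal 162.1), a beta-tubulin gene, hsp-1 (125.3), a chaperone gene, gpd-1 (122.9), a glycolytic enzyme gene, and act-2 (92.29), an actin gene.

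Germ granule genes had peaks at 4 of 20 starts (20%, odds ratio 8.24, adjusted exact p = 0.00696): pgl-3 (signal 164.5), simr-1 (90.04), glh-2 (87.10) and ife-1 (85.39). Genes of heterochromatin and histone methylation had them at 5 of 29 starts (17.2%, odds ratio 6.87, adjusted exact p = 0.00464), with lin-35 (signal 114.0), set-2 (97.19), cec-5 (83.83) and met-1 (81.93) the strongest. This call was lost without replicate 2, where the odds ratio was 2.54 (adjusted exact p = 0.365). Histone genes had them at 8 of 72 starts (11.1%, odds ratio 4.14, adjusted exact p = 0.00464). his-59 and his-60 shared the peak with summit IV 7487790 (signal 294.2), and his-61 (201.6) and his-64 (111.8) followed, with summits 52 and 18 bp past the 3′ ends of these short genes. The histone call was lost with a window of 200 bp (odds ratio 1.79, adjusted exact p = 0.601), with the gene body or 500 bp upstream (2.03, adjusted exact p = 0.173) and with the stronger IDR peaks (4.08, adjusted exact p = 0.0880), and with 1000 bp the odds ratio was 6.92. Histone genes are near-identical copies in clusters, so the copy behind a peak is uncertain. Genes that share a peak were counted separately, which the p-values of the histone list do not allow for.

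Chemoreceptor genes, a family of sensory receptors, had peaks at 4 of 1310 starts (0.305% against 3.15% of other genes, odds ratio 0.0942, adjusted exact p = 1.4e-11): srw-95, sri-5, srd-44 and srh-269, with signal values of 104.3, 92.69, 85.24 and 76.66. F-box genes had 1 of 322 (fbxb-85, signal 128.9; odds ratio 0.101, adjusted exact p = 0.00464), nuclear hormone receptor genes 1 of 269 (nhr-49, signal 80.59; odds ratio 0.121, adjusted exact p = 0.0136) and C-type lectin genes 1 of 240 (clec-126, signal 105.5; odds ratio 0.136, adjusted exact p = 0.0250). Without replicate 2 the F-box odds ratio was 0.318 (adjusted exact p = 0.0793), and no nuclear hormone receptor gene had a peak. When only genes with a pooled candidate at their start were compared, none of these 4 families passed, and the chemoreceptor odds ratio was 0.396 (adjusted exact p = 0.167). In that comparison germ granule genes (odds ratio 3.93, adjusted exact p = 0.115) also no longer passed. Nor did genes of heterochromatin and histone methylation (3.79, adjusted exact p = 0.0831). Oocyte (odds ratio 6.204), ribosomal protein (3.26) and abundant genes (4.93) had lower odds ratios but passed. Histone genes also passed, with 8 of 24 and a higher odds ratio of 4.95 (adjusted exact p = 0.00665).

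The lists of nuclear RNAi targets, small RNA pathway genes and meiosis genes did not pass at gene starts. None of the 8 listed targets of germline nuclear RNAi had one (upper 95% exact bound 36.9%, Fisher's exact adjusted exact p = 1). Of 45 small RNA pathway genes, hrde-1 (signal 327.6), eri-1 (120.7) and eri-5 (108.2) had one (6.67%, odds ratio 2.35, adjusted exact p = 0.271). Of 31 meiosis genes, syp-4 (signal 207.0), cosa-1 (92.89) and coh-4 (83.12) had one (odds ratio 3.52, adjusted exact p = 0.126). This list passed without replicate 2 (odds ratio 5.09, adjusted exact p = 0.0304) and with the gene body or 500 bp upstream (4.53, adjusted exact p = 0.0109). Sperm genes had 1 of 21 (spe-39, signal 100.04; adjusted exact p = 0.644) and major sperm protein genes 0 of 31. Intestine (0 of 22), muscle (0 of 17), neuron (0 of 25), and hypodermis and cuticle genes (0 of 24) had none, each with an adjusted exact p of 1, and lists of this size allowed shares of up to 13.7 to 19.5%. Collagens (2 of 156, col-85 and col-63; adjusted exact p = 0.504), heat shock genes (1 of 14, hsp-3; adjusted exact p = 0.504) and MATH and BATH genes (0 of 73; adjusted exact p = 0.476) did not pass.

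**Figure D3:**
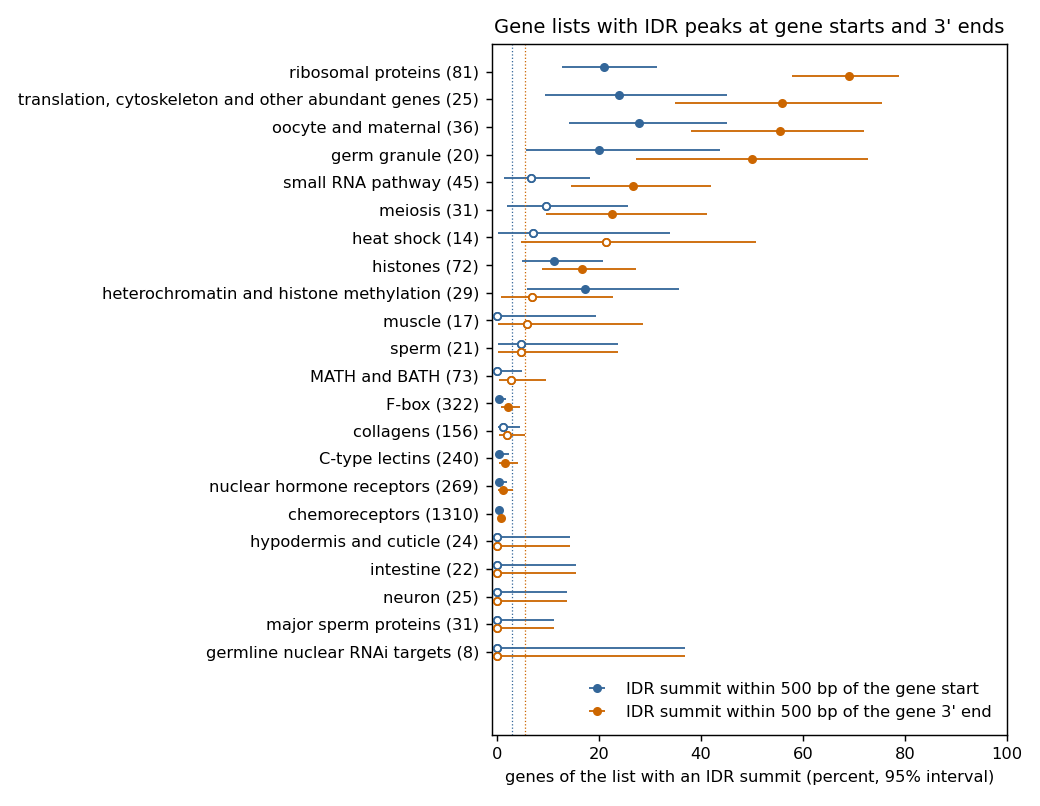
Percent of genes of each list (number of genes in brackets) with an IDR summit within 500 bp of the gene start (blue) or 3′ end (orange), with 95% exact binomial intervals; filled points passed an adjusted p of 0.05 and dotted lines mark the share of other protein-coding genes, as the median over lists. Ribosomal protein genes reached 20.99% at starts and 69.1% at 3′ ends, and the intestine list had 0 of 22 genes at either.

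The 8 nuclear sites among the strongest 25 included sites at ribosomal protein genes, snoRNA genes and hrde-1. After the rpl-3 summit came III 10746545 (signal 386.8), in an exon and 36 bp past the 3′ end of ran-1, a GTPase gene of nuclear transport, with no gene start within 1000 bp. Then came V 8500577 (347.5) at the snoRNA gene ZK994.7, which also had the tRNA gene ZK994.t2 within 1000 bp. The summit at IV 7083487 (345.2) lay 229 bp inside Y43B11AR.3, with the snoRNA gene Y43B11AR.7 nearby, and 209 bp past the 3′ end of rps-4. Next were V 12303639 (337.1) at the snoRNA gene C51F7.4, and III 6374002 (332.5) near the snoRNA gene C16A3.11 and 95 bp past the 3′ end of rps-13. The list ended with III 4176440 (327.6) at the start of C16C10.13, 281 bp upstream of hrde-1, and III 13464664 (323.9), 156 bp upstream of kel-3 and 12 bp past the 3′ end of ant-1.1. These 8 ranked between 20 and 63 in replicate 1 and between 21 and 33 in replicate 2.

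The next question was how peaks were spread over chromosomes. X held 118 of 1319 nuclear peaks (8.95%, interval 7.46 to 10.6%), against 9.50% of background candidates, and no difference was detected by Fisher's exact test (odds ratio 0.936, 0.765 to 1.14, exact p = 0.532). X makes up 17.7% of the nuclear genome, and against random nuclear positions the odds ratio was 0.457 (exact p = 6.9e-18). This result moved with the choice of sites: the odds ratio was 0.487 (exact p = 2.8e-11) without replicate 2, and 1.42 (exact p = 0.00125) against the upper tercile of the background by signal. Among peaks away from tRNA, snoRNA and snRNA genes, 18 of 986 lay on X (1.83%) against 9.23% of the background (odds ratio 0.183, exact p = 3.9e-21), a split chosen after the data were examined. On the autosomes, the arms (outer terciles by length) held 54.95% of peaks and 63.4% of background candidates (odds ratio 0.705, exact p = 5.7e-09). Against the upper tercile of the background by signal the arm odds ratio was 0.886 (exact p = 0.0535).

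The locus of the tagged gene was examined because a transgene can leave its own signature. hrde-1 lies at III 4172337 to 4176159 on the minus strand, and 5 IDR peaks lay within 20 kb of it, where random autosomal windows of that size held 0.631 on average. A share of 0.0102 of 10000 random windows held as many. The share was 0.002 with 10 kb on either side (5 peaks) and 0.0281 with 50 kb (6 peaks). The 5 summits lay at 4176440 (signal 327.6, upstream of the gene), 4174294 (112.5, inside it), 4172545 (156.7) and 4172333 (202.9) at its 3′ end, and 4171175 (114.4) beyond it. unc-119, a marker often used in worm transgenes, had 0 IDR peaks within 20 kb and 1 within 50 kb. Whether unc-119 was used in this strain is not given in the sources used here.

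**Figure D4:**
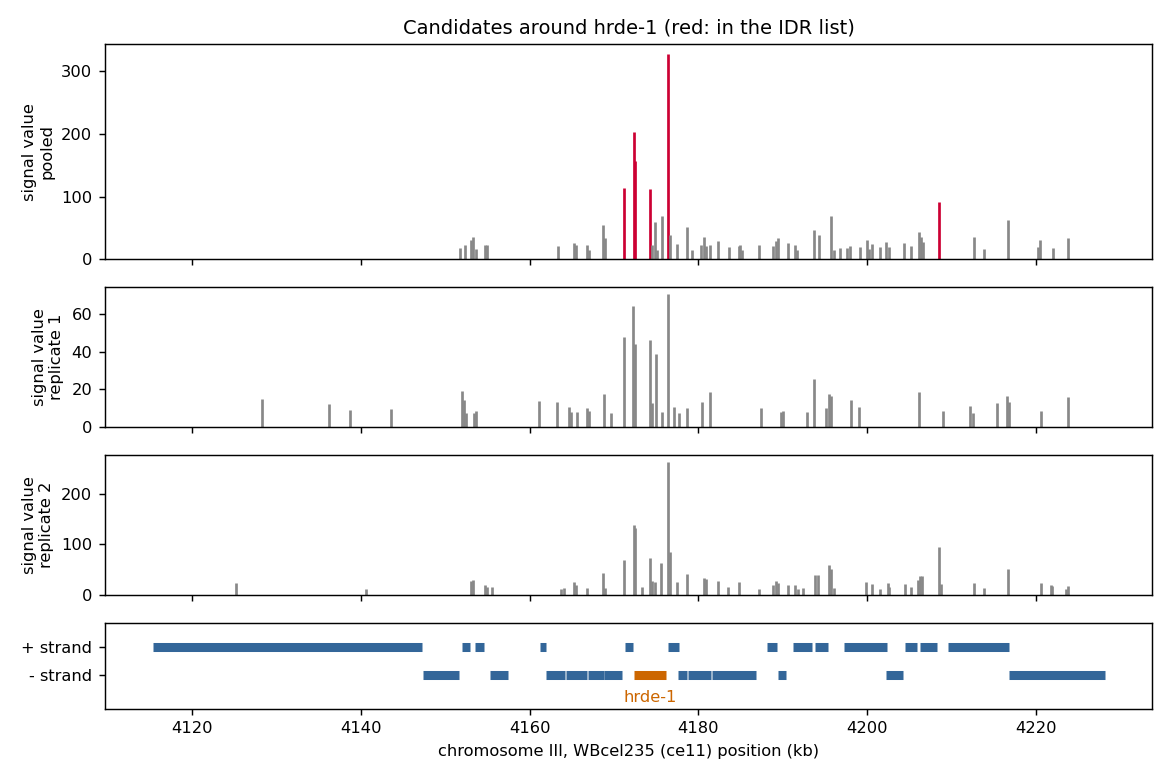
Signal values (authors' scores, scale not stated) of candidate sites on chromosome III around hrde-1 in the pooled, replicate 1 and replicate 2 lists, with genes by strand in the lowest panel. Sites in the IDR list are red; 5 lie within 20 kb of hrde-1, the highest at 327.6.

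The replicates were compared at the 1341 IDR peaks. A candidate of replicate 1 had its summit in 1289 of them, one of replicate 2 in 1332, and both in 1282. Across those 1282 peaks the signal values of the replicates had a Spearman's rho of 0.466 (permutation p = 1e-05, the smallest the permutations can give), and 0.439 across the 1261 nuclear ones. Peaks of 2 libraries are not independent replicates. The peaks were also the strongest candidates of the reads pooled from these same replicates. With that selection, neither rho and its p nor the shares that follow measure reproducibility over all candidates. Of the 1341 peaks, 787 (58.7%, exact interval 56.0 to 61.3%) were among the top 1341 candidates of both replicates, 910 among those of replicate 1 and 1168 among those of replicate 2. By class, snoRNA and snRNA peaks were among the top candidates of both most often in the nuclear genome (74.5% and 73.7%), and protein-coding 3′ ends followed with 60.8%. tRNA peaks reached 53.3% and protein-coding starts 54.1%. With the top 2682 candidates in place of the top 1341, the share of all peaks was 83.7%.

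**Figure D5:**
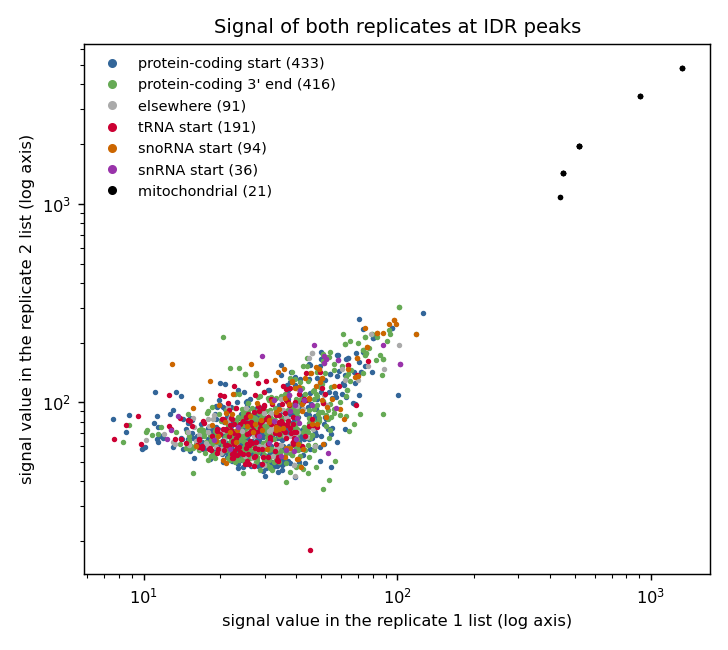
Signal value in the replicate 2 list against that in the replicate 1 list (both log axes; authors' scores, scale not stated) for the 1282 IDR peaks with a candidate in both, coloured by class of site. The 21 mitochondrial peaks lie above all nuclear peaks on both axes, and points of peaks that share an interval overlap.

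The last comparison was of sequence. IDR peaks were richer in G and C than background candidates, with a mean of 39.7% ± 7.33 (SD, n = 1341) against 37.5% ± 8.69 (SD, n = 27924) in 200 bp around the summit, a difference of 2.22 percentage points (permutation p = 1e-05, the smallest possible). Against background matched for GC content and for nearness to gene starts, 189 of 2080 6-mers differed at an adjusted p of 0.05 by Fisher's exact test, 135 more frequent and 54 less frequent. The first was CGAACC, found at 15.4% of IDR peaks and 6.40% of matched candidates (odds ratio 2.67, adjusted exact p = 2.1e-21), followed by GTTCGA (19.4% against 10.1%) and GAACCC (13.1% against 5.996%). Peaks at near-identical tRNA genes were counted as separate sites, which the p-values of 6-mers do not allow for. AATAAA, the core signal for polyadenylation, was found at 43.0% against 35.2% (adjusted exact p = 9.4e-06). The background was not matched for nearness to 3′ ends, where IDR peaks lay more often, and the strands were merged. The AATAAA difference is therefore not separate from the location of the peaks. Among the less frequent 6-mers CTGAAA had the lowest p, at 26.2% against 34.6% (adjusted exact p = 4.2e-07). The number of more frequent 6-mers was 65 without replicate 2 and 143 without replicate 1. Without sites at tRNA, snoRNA and snRNA genes it was 63. Without these and mitochondrial peaks CGAACC was at 6.29% against 4.44% (odds ratio 1.45, adjusted exact p = 0.169), and GCGCGA came first, at 10.85% against 3.98% (odds ratio 2.94, adjusted exact p = 1.3e-12).

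No difference in strength was detected between peaks at gene starts and the others. The median signal at gene starts was 101.5 (quartiles 84.54 and 126.7, n = 857) against 99.66 (84.26 and 128.1, n = 484), and the difference of 1.79 did not pass a two-sided permutation test (p = 0.504). Without replicate 2 the difference was −0.57 (permutation p = 0.455). That value is in the signal of the replicate 1 list, so its size cannot be set against 1.79.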

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

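The alternatives without mitochondrial peaks, without sites at tRNA, snoRNA and snRNA genes, with random nuclear positions, each replicate left out for gene types other than tRNA, lists at 3′ ends and X by class of site, and all those of the 3′ end result and of the snoRNA, snRNA and protein-coding shares were chosen after the data were examined; the others were planned. Of the main results under each alternative, 67 planned and 44 later ones kept their direction and side of the threshold, or, for counts, stayed within 1.5 times. This held under every alternative run for gene starts (odds ratio 2.21 to 4.25), 3′ ends (2.70 to 16.97), tRNA (7.23 to 17.998), snoRNA (10.04 to 26.4) and snRNA genes (6.62 to 21.7). It also held for introns (0.223 to 0.347), intergenic sites (1.65 to 2.27), repeats (0.366 to 0.625), GC content (0.809 to 4.45 percentage points higher) and rho (0.366 to 0.484). The X odds ratio did not: it was 1.02 in the stronger part of the IDR peaks, 1.42 against the upper tercile of the background, 0.457 against random nuclear positions, 0.183 without small RNA gene sites, 0.0888 with both of these, and 0.487 to 0.890 with each replicate left out. Against the upper tercile of the background the exon odds ratio was 1.02 and the arm odds ratio 0.886, neither past the threshold. In the stronger part of the IDR peaks the peak count was 670 by construction, the called lists at gene starts numbered 4 and the more frequent 6-mers 68. The called lists numbered 2 with a window of 200 bp and 4 among genes with a candidate at their start. The more frequent 6-mers numbered 363 against random positions, 83 in 100 bp, 63 without small RNA gene sites, and 65 to 143 with each replicate left out. The share of peaks among the top candidates of both replicates was 54.4% when a candidate had to overlap much of the peak and 83.7% with the top 2682. The signal difference between peaks at gene starts and others was −0.57 to 0.76 with each replicate left out, in the signal values of the other replicate's list. For single lists, gene types and X by class of site, 142 planned and 103 later alternatives gave the same call, 23 planned and 3 later ones lost a call, and 2 planned and 5 later ones gained one. The other changes were of direction, in lists and gene types past the threshold in neither setting. Sperm genes had an odds ratio of 0 in the stronger part of the IDR peaks and with a window of 200 bp, and 0.874 at 3′ ends. Heat shock genes had 0 in the stronger part and without replicate 2, and 2.64 without replicate 1. With the gene body or 500 bp upstream muscle genes had 2.51 and neuron genes 1.64, and muscle genes had 1.09 at 3′ ends. Small RNA pathway genes had 0.917 among genes with a candidate at their start. Antisense RNA genes, not past the threshold, had an odds ratio of 0.946, and of 1.43 and 1.60 with each replicate left out. Smaller sets of peaks or genes lower the counts by construction; the cause of the other changes was not tested. X against random positions on the same chromosomes was not run, since that background fixes the share. With 2 replicates, unknown depth and no control analysed here, recovery that does not depend on HRDE-1 could not be measured.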

Other observations

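The comparisons at 3′ ends and of X by class of site, the tRNA families, and the tests on tRNA gene copies, neighbouring starts, somatic gene lists and the flanks of hrde-1, and those without mitochondrial peaks, were chosen only after the result was seen; the tests of all IDR peaks against background matched for GC content were not.

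At 3′ ends, the lists of protein synthesis, oocyte and small RNA genes had peaks far more often than other genes. Of 22 lists tested by Fisher's exact test, 11 passed an adjusted p of 0.05 at 3′ ends, 7 higher and 4 lower. Ribosomal protein genes had a peak at 56 of 81 3′ ends (69.1% against 5.15% of other genes, odds ratio 41.2, adjusted exact p = 9.1e-51), with rps-4 (signal 345.2), rps-13 (332.5), rpl-12 (312.4) and rpl-3 (308.3) the strongest. The summits of rps-4, rps-13 and rpl-12 also lay within 1000 bp of the starts of snoRNA genes (Y43B11AR.7, C16A3.11 and JC8.15). Oocyte and maternal genes had 20 of 36 (55.6%, odds ratio 22.2), led by cpg-1 (signal 297.3), cpg-2 (265.6), cey-2 (227.6) and puf-3 (188.4). Abundant genes of translation and the cytoskeleton had 14 of 25 (56%, odds ratio 22.5), among them tbb-2 (signal 242.7) and eef-2 (216.6). Germ granule genes had 10 of 20 (50%, odds ratio 17.6), led by cgh-1 (signal 287.0) and wago-4 (192.8). Without replicate 2 the germ granule odds ratio was 9.01 and the oocyte one 13.5, both still past the threshold.

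The small RNA pathway list, which did not pass at gene starts, had peaks at 12 of 45 3′ ends (26.7%, interval 14.6 to 41.9%, odds ratio 6.42, adjusted exact p = 1.2e-05). Besides hrde-1 (signal 202.9) these were the Argonaute genes wago-4, csr-1 (173.0), wago-1 (126.2), ergo-1 (77.26) and prg-1 (74.02), with mut-16 (181.1), rde-12 (160.0), nrde-2 (129.9), parn-1 (88.79), dcr-1 (81.84) and hrde-4 (77.30). Meiosis genes had 7 of 31 (odds ratio 5.13, adjusted exact p = 0.00272) and histone genes 12 of 72 (odds ratio 3.53, adjusted exact p = 0.00123). Whether starts and 3′ ends differed for these lists was not tested. Lower were chemoreceptors (10 of 1310, odds ratio 0.126), nuclear hormone receptors (3 of 269, 0.195), F-box genes (7 of 322, 0.385) and C-type lectins (4 of 240, 0.294). Without replicate 2 these odds ratios were 0.0838, 0.123, 0.259 and 0.497, and C-type lectins no longer passed (adjusted exact p = 0.113). Without replicate 1, F-box genes were at 0.221 and nuclear hormone receptors at 0.132. Genes of heterochromatin and histone methylation (2 of 29) and collagens (3 of 156) did not pass. Without replicate 2 both lists did (odds ratios 3.48 and 0.107, adjusted exact p = 0.0404 and 0.00544). Heat shock genes (3 of 14), sperm genes (1 of 21), MATH and BATH genes (2 of 73) and muscle genes (1 of 17, dys-1) did not pass. Nuclear RNAi targets (0 of 8), major sperm proteins (0 of 31), intestine (0 of 22), neuron (0 of 25), and hypodermis and cuticle genes (0 of 24) had no peak at a 3′ end.

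Among small RNA genes, 12 of 19 sls-2 genes, which encode the SL2 spliced leader of operons, and 0 of 12 sls-1 genes had a peak. Each family is made of close copies, so the copy is uncertain. rpr-1, the RNA of RNase P, had a strong peak at I 13463938 (signal 286.3). Among amino acids with at least 10 nuclear tRNA genes, the share with a peak ran from 20 of 34 for alanine to 1 of 14 for phenylalanine. Of the IDR peaks at tRNA genes, 98 of 197 (49.7%) lay on X, against 36.7% of background candidates at tRNA genes (odds ratio 1.71, exact p = 0.00433). In replicate 1 alone this odds ratio was 1.12 (exact p = 0.617). X holds 276 of the 612 nuclear tRNA genes, and the share of tRNA genes with a peak there (43.1%) was like that on II (43.9%), III (40.6%) and I (39.4%), with 26.8% on IV and 21.8% on V. Away from tRNA, snoRNA and snRNA genes, X held 1.23% of the top sites of replicate 1 and 1.93% of those of replicate 2 (odds ratios 0.101 and 0.171).

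The tRNA peaks may in part reflect reads shared between near-identical gene copies. Of 612 nuclear tRNA genes, 231 of 592 with a stretch of 30 bases that occurs elsewhere in the genome had a peak (39.02%), against 1 of 20 without one (odds ratio 12.1, interval 1.90 to 507, exact p = 0.00152). Of the 16 without a repeated stretch and with no other tRNA gene within 1000 bp, 0 had a peak (upper exact bound 20.6%), where random positions gave 1.21%. Base composition as the whole cause is argued against by an odds ratio of 13.2 (10.2 to 17.2) with GC-matched background, and 11.2 (8.67 to 14.5) without mitochondrial peaks. By whole sequence, 38 of 143 unique tRNA genes (26.6%) had a peak, against 194 of 469 others (41.4%). Only 20 genes lack a repeated stretch, so most of those 143 still share stretches of 30 bases with other places. Whether genes without repeats are inactive stays open, because the lists do not measure the activity of tRNA genes.

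Peaks at 3′ ends were weighed against 3 explanations. Starts of neighbouring genes are argued against as the whole cause: among sites over 500 bp from every gene start, 83.3% of IDR peaks and 22.7% of background candidates lay at 3′ ends (odds ratio 16.97, interval 13.3 to 21.9). So is base composition, since the odds ratio was 4.92 (4.34 to 5.58) with GC-matched background, and 4.80 (4.23 to 5.45) without mitochondrial peaks. Recovery of strongly transcribed genes of any tissue stays open. Of intestine and muscle genes 1 of 39 had a peak (2.56%, interval 0.0649 to 13.5%), against 20 of 36 oocyte genes (55.6%, 38.1 to 72.1%), but 69 of 105 ribosomal protein and abundant genes had one (65.7%, 55.8 to 74.7%). The lists hold no expression values, so how strongly the intestine and muscle genes were transcribed is unknown. Recovery tied to transcription in germ cells without a role of HRDE-1 also stays open. So does binding of HRDE-1 near the ends of germline transcripts. A control precipitation from worms without the tag, if the antibody is against GFP, would measure only recovery that needs no tagged protein. Recovery that needs the tagged protein but no specific binding would stay open.

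The peaks at hrde-1 may reflect extra copies of the locus in the transgenic strain. From 1 to 20 kb on either side of the gene, 37 pooled candidates were found, where 2522 windows around autosomal protein-coding genes with a similar number of gene starts (17 ± 2) held 12.9 on average, and a share of 0.0143 of these held as many. These windows overlapped one another, and windows around neighbours of hrde-1 were not left out. The share is therefore not taken over independent loci. The lists used here do not separate extra copies from binding along the region. Genome sequencing of the strain would test this, and no biological explanation was tested.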
